A study of Mus musculus with 24 samples.

How the data were processed

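Bulk RNA sequencing libraries were made from PDGFRb-positive cells sorted by flow cytometry from the white adipose tissue of C57BL/6 mice. The 24 libraries formed 8 groups of 3, named in the labels by sex, depot and subpopulation. Gonadal tissue gave the subpopulations labelled APC and FIP, and inguinal tissue gave DPP4_neg and DPP4_pos cells, from females (F) and males (M). The sort gates that separated FIP from APC were not given in the sources used here. Per the labels, RNA was extracted with Trizol and 0.5 ug of total RNA entered each library, prepared with the NEBNext Ultra II kit.

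Per the submitters' processing notes, the tools were Trim Galore 0.4.1, HISAT2 2.0.1, featureCounts 1.4.6 and DESeq2 1.6.3, with the build GRCm38 or mm10. The roles of these tools, the annotation, the strand setting and any filter were not given in the sources used here. The deposited values were a normalized signal per gene and library, made by the authors as read counts divided by 1 size factor per library. This origin was checked on the values: in each library 100% of the values were whole multiples of 1 step, within 0.01 read. The steps gave back the whole reads, 9152470 to 18221700 per library. The deposited table was treated as normalized signal in the main test, because the values are not counts.

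The table held 27179 genes, of which 14517 had a value of at least 10 in at least 3 libraries and were tested. Another 3643 genes were at 0 in every library. Genes without a symbol took at most 0.0765% of a library's reads. Of the gene identifiers, 25275 (93.0%) matched the reference annotation of GRCm38, which supplied chromosome, start and end. Without a stated strand setting, reads of overlapping sense and antisense genes cannot be told apart, so Hoxa11 and Hoxa11os are uncertain as separate genes. Genes with near-identical copies, such as Ifi202b, H2-Q7, Ly6c1 and the ribosomal protein genes, are uncertain for the same kind of reason.

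Values were put on the scale log2(value + 1), and limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group and a mean-variance trend over all 24 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14517 genes of a contrast. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and errors of fold changes are standard errors (SE). The comparisons were FIP with APC and DPP4_pos with DPP4_neg in each sex, male with female in each subpopulation, gonadal with inguinal cells (APC with DPP4_neg and FIP with DPP4_pos) in each sex, and the 4 differences of these between the sexes. All comparisons, the 35 gene lists and the rule for named genes were fixed before the data were examined.

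For each population or depot comparison, the rule took genes called in the same direction in both sexes, with all 3 libraries of a group above all 3 of the other in both sexes and a mean of at least 100 in the higher group. The 10 highest and 10 lowest by the smaller of the absolute log2 fold changes qualified. For each sex comparison the 8 highest and 8 lowest qualified, and for each difference between sexes the 5 highest and 5 lowest called genes, without the overlap condition. Up to 4 called members of each list were added, ranked by the absolute log2 fold change, averaged over the sexes where a comparison has both. Predicted and clone-named genes were left out of the naming, and some genes that the rule names are not reported here.

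Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 420 tests, and again with an estimated correlation and with fry. The preset gave 142 calls, the estimated correlation 2 and fry 286. The 2 calls that held with an estimated correlation were both for the committed preadipocyte list. In all 142 calls the median, the mean and the test had the same sign. Camera sets a list against all other genes, whereas fry tests whether the members move, on balance, in 1 direction.

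Where a group had 0 reads over its 3 libraries, the fold was computed against a floor of 3 counts over the group and is written as at least that fold. With 1 to 3 reads the ratio is given with its exact binomial 95% interval. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

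Libraries of a group were compared before averaging. Their log2 values correlated with r between 0.982 and 0.992, and the chi-square per degree of freedom lay between 1.61 and 25.4 over the 24 replicate pairs, so no pair agreed within sampling noise. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Each gene had 1 spread estimated over all 8 groups, so its SE was the same in every comparison of 2 groups. That SE can understate the error where a group varied more, as Dpp4 did in F_DPP4_neg (1150 to 4213). The deviations of same-numbered libraries from their group means correlated over 0.1 for every number in 1 of 28 pairs of groups. That pair was female DPP4_neg with female DPP4_pos, at r of 0.129, 0.201 and 0.105, and the pairing there comes from the values, not from the labels.

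The fit was tested on simulated counts with the real library sizes and dispersions and 1 mean per gene, taken over all 24 libraries. In each of the 12 contrasts between 2 groups, 200 of 14517 genes were changed. The real contrasts called 36.9% to 66.1% of the genes, so the simulation does not show how the fit behaves under such broad change. Recovery over these contrasts was 45.7% to 71.4% at 1.5-fold, 67.1% to 85.7% at 2-fold and 86.7% to 98.3% at 4-fold, with 3 to 15 false calls.

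Alternatives were pseudocounts of 0.25 and 5, no filter and a filter of 50, TMM scaling, quantile normalization, library weights and fits on the compared groups alone. Further alternatives were a fold threshold, replicate blocks, each library left out in turn, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.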

Results

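Gene expression was measured in PDGFRb-positive adipose progenitor cells of female and male mice from the gonadal depot (subpopulations APC and FIP) and the inguinal depot (subpopulations DPP4_neg and DPP4_pos), with 3 libraries in each of 8 groups. The series title names heterogeneity of adipose progenitors by sex and depot as the subject. Recovered reads per library ranged from 9152470 to 13394000 in F_APC, 13141200 to 15781200 in F_FIP, 10324600 to 11300500 in M_APC and 13114700 to 15477700 in M_FIP. They ranged from 15699000 to 17165500 in F_DPP4_neg, 14394800 to 18221700 in F_DPP4_pos, 13055700 to 15929300 in M_DPP4_neg and 14040200 to 15011100 in M_DPP4_pos. The 10 most abundant genes of a library took 11.1% to 19.5% of its reads.

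Sex and gate genes were read first as a check of the labels. Xist, the transcript of the inactive X chromosome, lay between 11954 and 19203 normalised counts in the 12 female libraries and between 0 and 5.80 in the 12 male libraries. The Y-linked gene Ddx3y lay between 2035 and 3213 in males and between 23.1 and 124 in females, with the highest female mean, 92.6 ± 28.3 (SD, n = 3), in F_APC. Dpp4, whose protein defined the inguinal gates, averaged 18872 ± 1791 (SD, n = 3) in F_DPP4_pos and 2496 ± 1565 in F_DPP4_neg, against 15439 ± 606 in M_DPP4_pos and 245 ± 11.6 in M_DPP4_neg. In the gonadal depot Dpp4 averaged 8437 ± 811 in F_FIP and 1272 ± 202 in F_APC, against 4819.7 ± 311 in M_FIP and 194 ± 30.5 in M_APC. Pdgfrb was present in every group, from 1770.2 ± 35.4 in F_FIP to 6152 ± 117 in M_APC (SD, n = 3).

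Over the 500 most variable genes, libraries of a group correlated with r between 0.924 and 0.982 across genes, and libraries of different groups with r between 0.0715 and 0.819. The leading principal components held 41.7%, 22.3%, 18.3% and 7.80% of the variance.

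**Figure D1:**
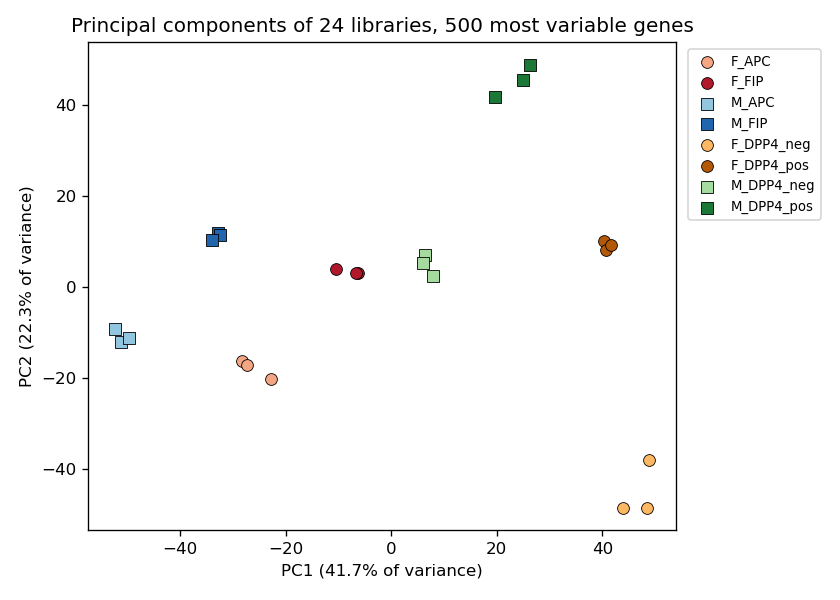
Positions of the 24 libraries on principal components 1 (41.7% of variance) and 2 (22.3% of variance) of log2(value + 1) over the 500 most variable genes, with a point per library, circles for females, squares for males and a colour per group. The 3 libraries of each group lie together.

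FIP and APC were compared to ask how the 2 gonadal subpopulations differ. FIP cells had far more transcript of Adamts16, a secreted metalloprotease gene (chromosome 13, 70727798 to 70841845, GRCm38), which was 22.6-fold higher than in APC in females (log2 fold change 4.50 ± 0.31 SE, limma, Benjamini-Hochberg adjusted p = 1.84e-11, n = 3 and 3). Its log2 fold change was 3.96 ± 0.31 in males. The Wnt ligand gene Wnt10b rose by 3.87 ± 0.32 and 6.25 ± 0.32 on the log2 scale in females and males, and Dact2, which encodes a binding partner of dishevelled, by 3.85 ± 0.16 and 5.93 ± 0.16. Nov (3.81 ± 0.26 and 5.66 ± 0.26), Gfra2 (3.90 ± 0.31 and 4.90 ± 0.31), Islr2 (3.59 ± 0.25 and 4.41 ± 0.25) and Aif1l (3.56 ± 0.19 and 3.44 ± 0.19) were also among the genes highest in FIP. APC cells had more Vtn, the gene of the adhesive glycoprotein vitronectin, with log2 fold changes of -3.13 ± 0.13 and -2.84 ± 0.13 for FIP against APC. The neurotrophin gene Ntf3 (-2.77 ± 0.21 and -3.50 ± 0.21), the receptor gene Cntfr (-2.82 ± 0.18 and -2.87 ± 0.18), Reep6 (-3.42 ± 0.40 and -3.21 ± 0.40) and the glutamate transporter gene Slc1a3 (-2.80 ± 0.15 and -2.57 ± 0.15) fell likewise.

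Counts of list members are over all genes tested, and where a bracket gives no count adjusted over the list alone, that count was the same. The interstitial progenitor list includes Dpp4 and Ly6c1. The gates of FIP and APC were not given, so whether a member was a sort marker is not known. All 16 tested genes of the interstitial progenitor list rose in FIP in females (camera adjusted p = 8.64e-17, adjusted p = 0.149 with an estimated correlation). All 16 rose in males as well (camera adjusted p = 2.97e-22, adjusted p = 0.114 with an estimated correlation). Among them Pi16 (chromosome 17, 29318796 to 29328903) rose by 3.22 ± 0.23 and 5.33 ± 0.23, Bmp7 by 3.01 ± 0.34 and 5.17 ± 0.34 and Efhd1 by 2.37 ± 0.25 and 5.34 ± 0.25 in females and males. Of 16 committed preadipocyte genes, 14 fell and 1 rose in females (camera adjusted p = 9.50e-12, adjusted p = 0.0469 with an estimated correlation), a call that held. In males 13 fell and 2 rose (camera adjusted p = 2.30e-07, adjusted p = 0.114 with an estimated correlation). Pparg, the central regulator of adipocyte differentiation, had log2 fold changes of -1.87 ± 0.13 and -1.79 ± 0.13, Car3 of -3.87 ± 0.27 and -1.69 ± 0.27 and Apoe of -3.10 ± 0.34 and -2.44 ± 0.34.

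Genes of adipocyte lipid storage were lower in FIP, 16 of 19 with 2 higher in females (camera adjusted p = 1.85e-07, adjusted p = 0.188 with an estimated correlation). In males 14 fell and 2 rose (camera adjusted p = 0.000253, adjusted p = 0.397 with an estimated correlation). Plin1, which encodes a coat protein of lipid droplets, had log2 fold changes of -4.06 ± 0.36 and -1.58 ± 0.36 in females and males, and Adipoq, the adiponectin gene, -3.95 ± 0.34 and -1.40 ± 0.34. In the WNT pathway list 10 of 17 genes rose and 3 fell in females (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0259, adjusted p = 0.324 with an estimated correlation). In males 8 rose and 3 fell (8 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00544, adjusted p = 0.188 with an estimated correlation). Sfrp4 rose by 2.50 ± 0.18 and 5.02 ± 0.18 and Sfrp2 by 2.07 ± 0.16 and 3.36 ± 0.16. In males 25 of 27 ribosomal protein genes were higher in FIP (26 higher adjusted over the list alone, camera adjusted p = 2.30e-07, adjusted p = 0.626 with an estimated correlation). Rpl4 had a log2 fold change of 0.57 ± 0.08. Of 22 proliferation genes 14 rose and 2 fell in male FIP (camera adjusted p = 0.00171, adjusted p = 0.604 with an estimated correlation). Top2a had a log2 fold change of 1.55 ± 0.28. Cholesterol synthesis genes fell in FIP, 11 of 18 with 2 higher (camera adjusted p = 0.00535, adjusted p = 0.636 with an estimated correlation) in females. In males they fell too, 9 of 18 with 1 higher (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.00746, adjusted p = 0.646 with an estimated correlation). In females genes of MHC class I presentation fell, 9 of 11 with 1 higher (camera adjusted p = 0.000124, adjusted p = 0.406 with an estimated correlation). Chemokine and cytokine genes fell, 13 of 21 with 4 higher (5 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.00615, adjusted p = 0.485 with an estimated correlation). F3-positive stromal genes fell, 7 of 8 (8 lower adjusted over the list alone, camera adjusted p = 0.000485, adjusted p = 0.149 with an estimated correlation). The oxidative phosphorylation list passed camera as lower, with 9 of 30 genes called lower (4 lower adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.733 with an estimated correlation). Of all tested genes 39.4% were called in this comparison in females.

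Markers of other cell types moved with these groups. In females 10 of 10 mesothelial markers were lower in FIP than in APC (camera adjusted p = 0.000200, adjusted p = 0.188 with an estimated correlation). Msln had a log2 fold change of -2.38 ± 0.39. The same held for 9 of 9 mural markers (camera adjusted p = 0.000142, adjusted p = 0.149 with an estimated correlation). Notch3 had a log2 fold change of -2.44 ± 0.32. It held for 12 of 13 macrophage markers (camera adjusted p = 7.70e-05, adjusted p = 0.406 with an estimated correlation). Ptprc had a log2 fold change of -2.58 ± 0.47. Likewise lower were 8 of 10 endothelial markers (camera adjusted p = 0.000747, adjusted p = 0.492 with an estimated correlation). Cldn5 had a log2 fold change of -1.35 ± 0.26. The adipocyte markers, all 8 of which are also in the lipid storage list, were lower for 7 of 7 tested in females (camera adjusted p = 6.68e-06, adjusted p = 0.167 with an estimated correlation). In males 6 fell (camera adjusted p = 0.00392, adjusted p = 0.397 with an estimated correlation). Immediate early genes, which respond to tissue dissociation, were lower in FIP for 12 of 18 with 1 higher in females (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 9.60e-05, adjusted p = 0.446 with an estimated correlation). In males 11 fell and 2 rose (camera adjusted p = 0.0112, adjusted p = 0.656 with an estimated correlation). In male FIP 4 of 5 lymphocyte markers were lower (camera adjusted p = 0.0451, adjusted p = 0.459 with an estimated correlation). The lymphocyte call ended under quantile normalization (adjusted p = 0.0857), without replicate 2 of M_APC (adjusted p = 0.103), without replicate 3 of M_APC (adjusted p = 0.0522) and without replicate 1 of M_FIP (adjusted p = 0.0629). Over all tested genes 5719 were called between FIP and APC in females, 3091 higher and 2628 lower, and 5355 in males, 2741 higher and 2614 lower. Past 2-fold 748 were higher and 944 lower in females, and 827 and 745 in males. In both sexes 1861 genes were higher and 1464 lower, where independent lists would share 584 and 473, and 119 went in opposite directions.

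DPP4_pos and DPP4_neg cells were compared to ask how the 2 inguinal subpopulations differ. Pi16, a peptidase inhibitor gene, averaged 60832 ± 7696 in F_DPP4_pos and 6941 ± 3950.3 in F_DPP4_neg (SD, n = 3), a log2 fold change of 3.29 ± 0.23 SE (limma, Benjamini-Hochberg adjusted p = 1.58e-11). In males it averaged 71908 ± 6474 and 726 ± 78.9, a log2 fold change of 6.63 ± 0.23. Dpp4 itself (chromosome 2, 62330073 to 62412315), the gene of the sorted surface protein, rose by 3.11 ± 0.24 and 5.97 ± 0.24 in females and males. Igsf1 (3.55 ± 0.31 and 6.89 ± 0.31), Wnt10b (3.02 ± 0.32 and 6.19 ± 0.32), the hydroxysteroid dehydrogenase gene Akr1c18 (3.21 ± 0.48 and 6.77 ± 0.48) and Bmp8a (2.99 ± 0.37 and 4.15 ± 0.37) were also higher in DPP4_pos. Lamc3, which encodes a laminin chain, had log2 fold changes of -6.51 ± 0.36 and -6.56 ± 0.36. Frem1 (-4.63 ± 0.44 and -5.22 ± 0.44), Egflam (-4.75 ± 0.33 and -3.84 ± 0.33) and the chloride channel gene Ano1 (-4.31 ± 0.28 and -3.65 ± 0.28) fell with it. Ltf, the lactoferrin gene, had 0 reads in the M_DPP4_pos libraries and was at least 235-fold higher in M_DPP4_neg.

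Of 16 interstitial progenitor genes, 1 of which is the sorted gene Dpp4, 15 rose in DPP4_pos cells of females (camera adjusted p = 6.40e-11, adjusted p = 0.251 with an estimated correlation). In males 16 rose (camera adjusted p = 2.21e-16, adjusted p = 0.149 with an estimated correlation). Bmp7 rose by 2.78 ± 0.34 and 7.47 ± 0.34. Committed preadipocyte genes fell, 14 of 16 with 1 higher in females (1 higher and 15 lower adjusted over the list alone, camera adjusted p = 1.78e-08, adjusted p = 0.109 with an estimated correlation). In males 15 fell (camera adjusted p = 1.10e-13, adjusted p = 0.0434 with an estimated correlation), where the call held. Fabp4, a fatty acid binding protein gene, had log2 fold changes of -3.57 ± 0.17 and -4.08 ± 0.17, Cd36, a fatty acid uptake gene, of -3.24 ± 0.13 and -3.60 ± 0.13 and Sparcl1 of -3.10 ± 0.13 and -5.30 ± 0.13.

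Cholesterol synthesis genes were lower in DPP4_pos, 14 of 18 in females (16 lower adjusted over the list alone, camera adjusted p = 9.95e-07, adjusted p = 0.377 with an estimated correlation). In males 14 fell (camera adjusted p = 1.24e-07, adjusted p = 0.329 with an estimated correlation). Sqle, the squalene epoxidase gene, had log2 fold changes of -2.34 ± 0.14 and -2.48 ± 0.14, and Cyp51 of -1.69 ± 0.18 and -2.56 ± 0.18. F3-positive stromal genes were lower as well, 6 of 8 with 1 higher in females (camera adjusted p = 0.000478, adjusted p = 0.149 with an estimated correlation). In males 6 fell and 1 rose (camera adjusted p = 9.60e-05, adjusted p = 0.128 with an estimated correlation), among them Clec11a (-2.30 ± 0.13 and -2.90 ± 0.13) and Mgp (-1.94 ± 0.18 and -3.15 ± 0.18). In females 13 of 18 interferon response genes rose (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000253, adjusted p = 0.636 with an estimated correlation), among them Irf7 (1.33 ± 0.13) and Bst2 (1.24 ± 0.16). Ribosomal protein genes passed camera as higher, with a median of 0.23 in females (7 higher adjusted over the list alone, camera adjusted p = 0.00651, adjusted p = 0.790 with an estimated correlation) that quantile normalization turned to -0.02 (adjusted p = 0.610). The male median was 0.18 (7 higher adjusted over the list alone, camera adjusted p = 0.0375, adjusted p = 0.830 with an estimated correlation). That call ended under quantile normalization (camera adjusted p = 0.310), without replicate 2 or 3 of M_DPP4_neg (adjusted p = 0.401 and adjusted p = 0.204) and without replicate 3 of M_DPP4_pos (adjusted p = 0.11). Lipid storage genes fell in females, 14 of 19 with 2 higher (camera adjusted p = 0.0137, adjusted p = 0.568 with an estimated correlation).

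Markers of other cell types and immediate early genes moved with the inguinal groups. All 9 tested markers of mammary and other epithelium were lower in F_DPP4_pos than in F_DPP4_neg (camera adjusted p = 4.59e-05, adjusted p = 0.149 with an estimated correlation), among them Epcam (-4.78 ± 0.52) and Cdh1 (-4.71 ± 0.66). So were 13 of 13 macrophage markers (camera adjusted p = 0.000967, adjusted p = 0.502 with an estimated correlation), with Laptm5 at -2.04 ± 0.31 and Lyz2 at -1.71 ± 0.37. Adipocyte markers were lower in F_DPP4_pos, 6 of 7 (camera adjusted p = 0.00790, adjusted p = 0.406 with an estimated correlation). Of the mesothelial markers 6 of 10 were lower (camera adjusted p = 0.0141, adjusted p = 0.397 with an estimated correlation). The mesothelial call ended under quantile normalization (adjusted p = 0.0787). In males 7 of 13 macrophage markers were lower in DPP4_pos (camera adjusted p = 0.0234, adjusted p = 0.673 with an estimated correlation). The male macrophage call ended under quantile normalization (adjusted p = 0.0921) and without replicate 1 of M_DPP4_neg (adjusted p = 0.0519). Lower in male DPP4_pos were also 6 of 9 mural markers (camera adjusted p = 0.0191, adjusted p = 0.373 with an estimated correlation). Immediate early genes fell there, 12 of 18 with 3 higher (4 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.00849, adjusted p = 0.646 with an estimated correlation). The test called 7216 genes in females, 3288 higher and 3928 lower, and 7334 in males, 3660 higher and 3674 lower. Past 2-fold 747 were higher and 1842 lower in females, and 918 and 1661 in males. In both sexes 2068 were higher and 2097 lower, against 829 and 994 for independent lists, and 488 went in opposite directions.

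**Figure D2:**
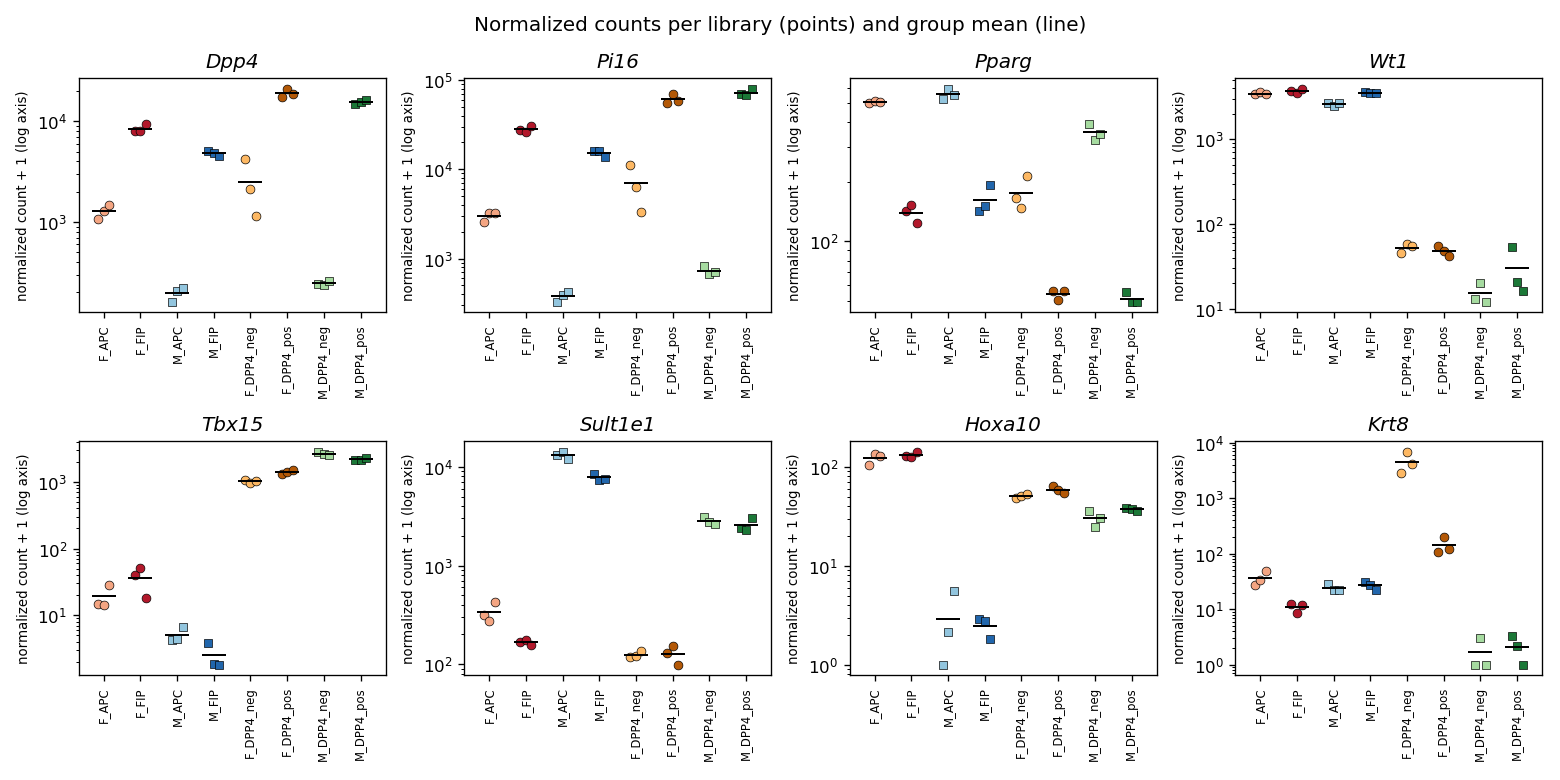
Normalised counts of named genes per library on a log axis of value + 1, with a point per library and a bar at the mean of the 3 libraries of each of the 8 groups. Pi16 averaged 71908 in M_DPP4_pos and 726 in M_DPP4_neg.

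FIP and DPP4_pos profiles were set side by side across depots. Across 14517 genes the log2 fold changes of FIP against APC correlated with those of DPP4_pos against DPP4_neg at r = 0.464 in females and r = 0.562 in males (Spearman rho 0.406 and 0.501). Genes are not independent replicates, and the comparisons share no library. In females 1573 genes were higher and 1292 lower in both comparisons, against 700.1 and 711 for independent lists, and 709 went in opposite directions. In males 1692 were higher and 1583 lower, against 691 and 662, and 441 were opposite.

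Male and female APC were compared to ask how this gonadal subpopulation differs between the sexes. The labels name only gonadal tissue for both sexes. In APC and FIP the effect of sex therefore cannot be told apart from that of the position of the fat pad. Sult1e1, the estrogen sulfotransferase gene (chromosome 5, 87575968 to 87591611), averaged 13086 ± 1043 in M_APC and 339 ± 79.8 in F_APC (SD, n = 3), a log2 fold change of 5.29 ± 0.14 SE (limma, Benjamini-Hochberg adjusted p = 3.04e-19). Lrrn1 (6.05 ± 0.40), the phosphodiesterase gene Pde11a (5.27 ± 0.22) and Dok7 (5.10 ± 0.40) were higher in males too. Ngfr, the low-affinity nerve growth factor receptor gene, had a log2 fold change of -8.51 ± 0.57, Cntn1 of -7.26 ± 0.30, Emb of -6.09 ± 0.28 and Hoxa10 of -5.74 ± 0.35. The M_APC libraries had 0 reads of Hoxa11os, Hoxa11 and Ptpn5, which were at least 127-fold, 102-fold and 90.5-fold higher in F_APC.

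All 27 ribosomal protein genes were lower in male APC (camera adjusted p = 6.90e-16, adjusted p = 0.397 with an estimated correlation), for example Rps9 at -1.03 ± 0.10. Interferon response genes were lower too, 16 of 18 with 1 higher (camera adjusted p = 5.33e-07, adjusted p = 0.474 with an estimated correlation), among them Ifit1 (-2.08 ± 0.22) and Oas1a (-2.07 ± 0.15). Of 16 interstitial progenitor genes 11 fell (camera adjusted p = 3.80e-06, adjusted p = 0.406 with an estimated correlation), with Dpp4 at -2.71 ± 0.24 and Pi16 at -2.99 ± 0.23. Dpp4 averaged 1272 in F_APC against 8437 in F_FIP, and 194 in M_APC against 4820 in M_FIP. Whether FIP cells left among the F_APC cells enter these differences was not tested. Cholesterol synthesis genes rose, 15 of 18 (camera adjusted p = 4.80e-07, adjusted p = 0.372 with an estimated correlation), among them Fdps (1.77 ± 0.16). Genes of MHC class I presentation fell, 7 of 11 with 1 higher (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.000775, adjusted p = 0.490 with an estimated correlation). Genes of oxidative phosphorylation fell, 15 of 30 (camera adjusted p = 0.00110, adjusted p = 0.733 with an estimated correlation). Collagen genes fell, 6 of 12 (camera adjusted p = 0.0145, adjusted p = 0.673 with an estimated correlation). The collagen call ended under quantile normalization (adjusted p = 0.135). All 6 tested muscle markers were higher in male APC (camera adjusted p = 0.00583, adjusted p = 0.397 with an estimated correlation). Conversely, 8 of 10 mesothelial markers were lower (9 lower adjusted over the list alone, camera adjusted p = 0.0157, adjusted p = 0.397 with an estimated correlation). In all 6452 genes were called, 3249 higher and 3203 lower in males. Past 2-fold 904 were higher and 867 lower.

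In FIP cells the same sex comparison gave 5404 called genes, 2649 higher and 2755 lower in males, or 962 and 597 past 2-fold. Sult1e1 rose by 5.55 ± 0.14, the terminal complement gene C7 by 4.47 ± 0.13 and Nt5e, an ectonucleotidase gene, by 4.98 ± 0.14 (SE, n = 3 and 3). Cntn1 had a log2 fold change of -8.81 ± 0.30, Ngfr of -7.69 ± 0.57 and Greb1, an estrogen-regulated gene, of -5.68 ± 0.46 (limma, Benjamini-Hochberg adjusted p = 4.52e-10 for Greb1). Cholesterol synthesis genes rose, 14 of 18 with 1 lower (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.01e-08, adjusted p = 0.303 with an estimated correlation). Lipid storage genes rose, 14 of 19 (16 higher adjusted over the list alone, camera adjusted p = 0.000101, adjusted p = 0.373 with an estimated correlation), led by the leptin gene Lep (3.08 ± 0.45). Interferon response genes fell, 13 of 18 (15 lower adjusted over the list alone, camera adjusted p = 2.92e-05, adjusted p = 0.560 with an estimated correlation). Ifit1 had a log2 fold change of -1.96 ± 0.22. Of 8 inguinal identity genes 6 were lower and 1 higher in males (camera adjusted p = 0.0192, adjusted p = 0.372 with an estimated correlation), among them Hoxc10 (-5.53 ± 0.25) and Tbx15 (-3.82 ± 0.30). Ribosomal protein genes fell, 18 of 27 (19 lower adjusted over the list alone, camera adjusted p = 3.87e-05, adjusted p = 0.683 with an estimated correlation). TGF-beta response and contractile genes rose, 7 of 14 with 1 lower (camera adjusted p = 0.00324, adjusted p = 0.202 with an estimated correlation). Collagen genes fell in male FIP, 8 of 12 with 1 higher (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0182, adjusted p = 0.674 with an estimated correlation). The collagen call ended under quantile normalization (adjusted p = 0.118), without replicate 1 of F_FIP (adjusted p = 0.0559) and without replicate 1 of M_FIP (adjusted p = 0.0785). Matrix remodelling genes fell, 11 of 24 with 3 higher (camera adjusted p = 0.0174, adjusted p = 0.510 with an estimated correlation). The matrix remodelling call ended under quantile normalization (adjusted p = 0.0552).

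Markers of macrophages (11 of 13) were higher in male FIP (camera adjusted p = 0.000235, adjusted p = 0.458 with an estimated correlation). Ptprc had a log2 fold change of 2.95 ± 0.47. So were markers of endothelium, 8 of 10 (9 higher adjusted over the list alone, camera adjusted p = 3.12e-05, adjusted p = 0.397 with an estimated correlation). Cldn5 had a log2 fold change of 2.18 ± 0.26. Adipocyte markers were higher too, 7 of 7 (camera adjusted p = 0.00188, adjusted p = 0.377 with an estimated correlation). Mural markers were higher for 6 of 9 (camera adjusted p = 0.00879, adjusted p = 0.303 with an estimated correlation) and muscle markers for 5 of 6 (camera adjusted p = 0.0308, adjusted p = 0.490 with an estimated correlation). The muscle call ended under quantile normalization (adjusted p = 0.0633). Immediate early genes rose in male FIP, 9 of 18 with 4 lower (camera adjusted p = 0.0330, adjusted p = 0.705 with an estimated correlation). Their call ended without replicate 3 of M_FIP (adjusted p = 0.0632).

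Inguinal DPP4_neg cells differed between the sexes in 8332 genes, 3934 higher and 4398 lower in males, or 1132 and 1476 past 2-fold. Replicates 1 and 2 of M_DPP4_neg had the highest chi-square per degree of freedom of all replicate pairs (25.4). Replicate 1 had the lowest library weight (0.194), and replicate 2 the most genes with a read (20103). Without replicate 1 the test called 8068 genes. Ifi202b was higher in males by 6.21 ± 0.24 on the log2 scale, C7 by 4.18 ± 0.13, Sult1e1 by 4.50 ± 0.14, the stress-induced cytokine gene Gdf15 by 4.09 ± 0.24 and Agt, the angiotensinogen gene, by 3.77 ± 0.12 (SE, n = 3 and 3, limma, Benjamini-Hochberg adjusted p = 9.72e-18 for Agt). Female DPP4_neg libraries held epithelial transcripts. Krt8, a keratin gene of simple epithelia (chromosome 15, 101996711 to 102004342), averaged 4567 ± 2011 (SD, n = 3) in F_DPP4_neg against 2 reads in all M_DPP4_neg libraries, a ratio of 6374 with a 95% counting interval from 1764 to 52639. Cldn4 had a ratio of 4617 (1278 to 38127), and the fibrinogen gene Fgg, with 0 reads in M_DPP4_neg, was at least 566-fold higher in females. All 9 tested markers of mammary and other epithelium were lower in males (camera adjusted p = 1.29e-06, adjusted p = 0.114 with an estimated correlation). Adipocyte markers were higher in male DPP4_neg, 5 of 7 (camera adjusted p = 0.0226, adjusted p = 0.490 with an estimated correlation). This adipocyte call ended without replicate 1 of M_DPP4_neg (adjusted p = 0.0539). Endothelial markers were lower, 7 of 10 (8 lower adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.683 with an estimated correlation). The endothelial call ended under quantile normalization (adjusted p = 0.0749), without replicate 3 of F_DPP4_neg (adjusted p = 0.0589) and without replicate 3 of M_DPP4_neg (adjusted p = 0.102). Immediate early genes rose, 10 of 18 with 3 lower (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0275, adjusted p = 0.683 with an estimated correlation). The immediate early call ended under quantile normalization (adjusted p = 0.954), without replicate 1 of F_DPP4_neg (adjusted p = 0.05) and without replicate 2 of F_DPP4_neg (adjusted p = 0.061).

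Chemokine and cytokine genes were higher in male DPP4_neg, 18 of 21 with 2 lower (camera adjusted p = 1.74e-08, adjusted p = 0.149 with an estimated correlation), led by Cxcl2 (3.47 ± 0.12), Cxcl5 (3.45 ± 0.24) and Saa3 (3.14 ± 0.25). All 11 genes of MHC class I presentation rose (camera adjusted p = 3.43e-07, adjusted p = 0.303 with an estimated correlation), with Nlrc5, a transactivator of these genes, at 2.46 ± 0.14. Interferon response genes, lower in male APC and FIP, were higher in male DPP4_neg, 13 of 18 with 1 lower (camera adjusted p = 0.00706, adjusted p = 0.742 with an estimated correlation). Complement genes rose, 8 of 11 with 1 lower (camera adjusted p = 0.00141, adjusted p = 0.383 with an estimated correlation). The complement call ended under quantile normalization (adjusted p = 0.0547). Cholesterol synthesis genes rose, 12 of 18 with 2 lower (camera adjusted p = 0.00790, adjusted p = 0.648 with an estimated correlation). F3-positive stromal genes rose, 6 of 8 with 1 lower (camera adjusted p = 0.00583, adjusted p = 0.240 with an estimated correlation). Of 31 HOX genes 17 were higher in males (camera adjusted p = 0.00230, adjusted p = 0.372 with an estimated correlation). Interstitial progenitor genes fell, 15 of 16 with 1 higher (camera adjusted p = 5.40e-07, adjusted p = 0.397 with an estimated correlation), with Bmp7 at -4.64 ± 0.34 and Dpp4 at -3.15 ± 0.24. In F_DPP4_neg replicates 1, 2 and 3 Dpp4 lay at 22.3%, 11.3% and 6.09% of its F_DPP4_pos mean, against 1.59% for the male groups. Of the 14 other genes of this list that were lower in males, 13 were highest in replicate 1. Committed preadipocyte genes rose, 9 of 16 (camera adjusted p = 0.000237, adjusted p = 0.226 with an estimated correlation), among them Vcam1 (2.32 ± 0.14) and Plin2 (1.88 ± 0.10).

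DPP4_pos cells differed between the sexes in 7638 genes, 3929 higher and 3709 lower in males, or 1021 and 1062 past 2-fold. The neutrophil chemokine genes Cxcl5, Cxcl2 and Cxcl3 were higher in males by 5.35 ± 0.24, 4.98 ± 0.12 and 4.25 ± 0.31 on the log2 scale, and Saa3, an acute phase gene, by 4.14 ± 0.25 (SE, n = 3 and 3, limma, Benjamini-Hochberg adjusted p = 1.14e-12 for Saa3). Pgr, the progesterone receptor gene, had a log2 fold change of -7.30 ± 0.46, Greb1 of -8.47 ± 0.46 and Ngfr of -6.95 ± 0.57. Chemokine and cytokine genes rose, 14 of 21 with 4 lower (camera adjusted p = 5.96e-06, adjusted p = 0.232 with an estimated correlation). Complement genes rose, 7 of 11 with 1 lower (camera adjusted p = 0.00247, adjusted p = 0.397 with an estimated correlation), with C7 at 4.47 ± 0.13 and Cfb at 1.85 ± 0.11. Lipid storage genes rose, 13 of 19 with 1 lower (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00314, adjusted p = 0.478 with an estimated correlation). Of the adipocyte markers 7 of 7 rose (camera adjusted p = 0.00210, adjusted p = 0.381 with an estimated correlation). Krt8 averaged 141 ± 50.7 (SD, n = 3) in F_DPP4_pos against 3 reads in all M_DPP4_pos libraries, a ratio of 124 (42.2 to 604). Genes of MHC class I presentation rose, 8 of 11 (camera adjusted p = 0.000747, adjusted p = 0.490 with an estimated correlation). Genes of glycolysis and hypoxia rose, 12 of 18 with 3 lower (camera adjusted p = 0.0330, adjusted p = 0.402 with an estimated correlation). The glycolysis call ended under quantile normalization (adjusted p = 0.122) and without replicate 2 of F_DPP4_pos (adjusted p = 0.0676). Matrix remodelling genes fell in male DPP4_pos, 12 of 24 with 5 higher (6 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.581 with an estimated correlation). The matrix remodelling call ended without replicate 3 of F_DPP4_pos (adjusted p = 0.0587).

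Across the 14517 genes, male against female fold changes correlated at r = 0.728 between APC and FIP and at r = 0.598 between DPP4_neg and DPP4_pos. Between depots r was 0.297 for APC with DPP4_neg and 0.425 for FIP with DPP4_pos.

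Gonadal APC and inguinal DPP4_neg cells were compared to ask how the depots differ. The transcription factor genes Tcf21 and Wt1 were high in the gonadal cells. Wt1 (chromosome 2, 105126529 to 105173614) averaged 3449.5 ± 108 in F_APC and 51.6 ± 6.28 in F_DPP4_neg (SD, n = 3), a log2 fold change of 6.04 ± 0.25 SE (limma, Benjamini-Hochberg adjusted p = 2.79e-16), and rose by 7.46 ± 0.25 in males. Tcf21 rose by 6.32 ± 0.39 and 8.70 ± 0.39 in females and males, the glutathione transferase gene Gsta3 by 4.40 ± 0.25 and 5.80 ± 0.25 and Pappa, an IGF-binding-protein protease gene, by 3.36 ± 0.34 and 3.20 ± 0.34. The T-box gene Tbx15 (chromosome 3, 99240348 to 99354260) had log2 fold changes of -5.80 ± 0.30 and -9.05 ± 0.30. Shox2 (-5.65 ± 0.41 and -6.81 ± 0.41), Irx2 (-5.47 ± 0.37 and -6.22 ± 0.37), the neurotrophic factor gene Gdnf (-6.28 ± 0.39 and -7.77 ± 0.39) and Il1rl1, the interleukin 33 receptor gene (-5.22 ± 0.21 and -6.87 ± 0.21), fell with it.

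Gonadal identity genes rose in APC, 6 of 6 in females (camera adjusted p = 0.000191, adjusted p = 0.114 with an estimated correlation). In males 5 rose (camera adjusted p = 0.00615, adjusted p = 0.188 with an estimated correlation). Collagen genes were lower in gonadal APC, 8 of 12 with 2 higher in females (camera adjusted p = 0.00341, adjusted p = 0.624 with an estimated correlation). In males 12 fell (camera adjusted p = 1.28e-05, adjusted p = 0.40 with an estimated correlation). Col1a1 had log2 fold changes of -2.01 ± 0.15 and -2.97 ± 0.15. In males interferon response genes were lower in APC, 17 of 18 (camera adjusted p = 1.30e-07, adjusted p = 0.425 with an estimated correlation). Rsad2 had a log2 fold change of -3.57 ± 0.23. Chemokine and cytokine genes fell, 17 of 21 with 2 higher (camera adjusted p = 5.67e-08, adjusted p = 0.149 with an estimated correlation), among them Il33 (-5.83 ± 0.14) and Cxcl13 (-7.20 ± 0.20). MHC class I genes fell with them, 11 of 11 (camera adjusted p = 9.55e-07, adjusted p = 0.329 with an estimated correlation). In females 21 of 31 HOX genes rose and 1 fell (23 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.35e-05, adjusted p = 0.158 with an estimated correlation). Hoxa5 had a log2 fold change of 2.55 ± 0.18. Lipid storage genes were higher in APC, 14 of 19 with 1 lower (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000511, adjusted p = 0.397 with an estimated correlation) in females. In males they rose also, 16 of 19 with 2 lower (camera adjusted p = 0.00591, adjusted p = 0.507 with an estimated correlation). In females committed preadipocyte genes rose, 12 of 16 (camera adjusted p = 0.000178, adjusted p = 0.215 with an estimated correlation). TGF-beta response and contractile genes fell in females, 11 of 14 with 2 higher (camera adjusted p = 0.0131, adjusted p = 0.303 with an estimated correlation). Interstitial progenitor genes were lower in female APC, 11 of 16 with 1 higher (camera adjusted p = 0.00779, adjusted p = 0.674 with an estimated correlation). The interstitial progenitor call ended without replicate 1 of F_DPP4_neg (adjusted p = 0.0601). The oxidative phosphorylation list passed camera as higher in female APC, with 12 of 30 genes called higher (10 higher adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.805 with an estimated correlation). Of all tested genes 59.0% were called in this comparison in females. The oxidative phosphorylation call ended without replicate 2 of F_APC (adjusted p = 0.115) and without replicate 3 of F_DPP4_neg (adjusted p = 0.103). In males all ribosomal protein genes fell, 27 of 27 (camera adjusted p = 6.44e-10, adjusted p = 0.510 with an estimated correlation). Inguinal identity genes fell, 6 of 8 with 1 higher (camera adjusted p = 0.0222, adjusted p = 0.373 with an estimated correlation). F3-positive stromal genes fell, 6 of 8 (camera adjusted p = 0.00201, adjusted p = 0.188 with an estimated correlation). Complement genes fell, 8 of 11 (9 lower adjusted over the list alone, camera adjusted p = 0.00141, adjusted p = 0.383 with an estimated correlation). Genes of glycolysis and hypoxia fell in males, 11 of 18 with 6 higher (camera adjusted p = 0.0346, adjusted p = 0.402 with an estimated correlation). The glycolysis call ended under quantile normalization (adjusted p = 0.173) and without replicate 1 of M_DPP4_neg (adjusted p = 0.0651).

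Immediate early genes were higher in gonadal APC, 14 of 18 with 4 lower in females (camera adjusted p = 1.18e-06, adjusted p = 0.373 with an estimated correlation). In males 14 rose and 3 fell (camera adjusted p = 0.000195, adjusted p = 0.474 with an estimated correlation), for example Btg2 (2.34 ± 0.08 and 1.89 ± 0.08). Endothelial markers were higher as well, 9 of 10 in females (camera adjusted p = 0.00378, adjusted p = 0.585 with an estimated correlation). In males 10 rose (camera adjusted p = 2.28e-05, adjusted p = 0.397 with an estimated correlation). Of the 10 mesothelial markers, 2 of which are also gonadal identity genes, 9 were higher in male APC (camera adjusted p = 0.00180, adjusted p = 0.287 with an estimated correlation). Adipocyte markers were higher in female APC, 6 of 7 (7 higher adjusted over the list alone, camera adjusted p = 0.00294, adjusted p = 0.397 with an estimated correlation). All 9 tested epithelial markers were lower in female APC (camera adjusted p = 3.43e-05, adjusted p = 0.149 with an estimated correlation). The test called 8569 genes in females, 3888 higher (45.4%) and 4681 lower, and 9599 in males, 4809 higher and 4790 lower. Past 2-fold 1054 were higher and 1967 lower in females, and 1676 and 1924 in males. Under quantile normalization the higher share in females was 56.6% of 9264 calls.

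Gonadal FIP and inguinal DPP4_pos cells were compared as the other pair of depots. Wt1 rose in FIP by 6.28 ± 0.25 and 7.08 ± 0.25 in females and males (limma, Benjamini-Hochberg adjusted p = 2.38e-16 and adjusted p = 5.85e-18, n = 3 and 3), Tcf21 by 5.97 ± 0.39 and 7.71 ± 0.39 and Eya2, a transcriptional coactivator gene, by 4.25 ± 0.17 and 4.47 ± 0.17. Lrrn2 (4.77 ± 0.30 and 6.07 ± 0.30), Cyp2s1 (4.72 ± 0.28 and 4.99 ± 0.28) and Dapk2 (5.21 ± 0.22 and 4.54 ± 0.22) were higher in FIP too. Tbx15 had log2 fold changes of -5.40 ± 0.30 and -9.84 ± 0.30, Irx1 of -5.85 ± 0.30 and -8.68 ± 0.30, the homeobox gene En1 of -4.61 ± 0.33 and -6.63 ± 0.33 and Il1r2, the decoy interleukin 1 receptor gene, of -4.10 ± 0.17 and -7.83 ± 0.17.

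Committed preadipocyte genes were higher in FIP than in DPP4_pos, 11 of 16 with 1 lower in females (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.28e-05, adjusted p = 0.149 with an estimated correlation). In males 11 rose and 1 fell (camera adjusted p = 0.000279, adjusted p = 0.232 with an estimated correlation). Cd36 had log2 fold changes of 1.68 ± 0.13 and 3.13 ± 0.13. Interferon response genes were lower in FIP, 15 of 18 in females (16 lower adjusted over the list alone, camera adjusted p = 5.16e-08, adjusted p = 0.406 with an estimated correlation). In males 17 fell (camera adjusted p = 5.16e-08, adjusted p = 0.406 with an estimated correlation). Isg15 had log2 fold changes of -1.95 ± 0.21 and -3.21 ± 0.21. MHC class I genes fell, 8 of 11 in females (10 lower adjusted over the list alone, camera adjusted p = 7.18e-05, adjusted p = 0.402 with an estimated correlation). In males 11 fell (camera adjusted p = 9.63e-07, adjusted p = 0.329 with an estimated correlation). Genes of glycolysis and hypoxia fell, 11 of 18 with 1 higher in females (camera adjusted p = 0.00221, adjusted p = 0.238 with an estimated correlation). In males 14 fell (camera adjusted p = 0.000268, adjusted p = 0.158 with an estimated correlation), among them the hexokinase gene Hk2 (-1.18 ± 0.08 and -1.79 ± 0.08). In males 18 of 22 proliferation genes rose (camera adjusted p = 0.000485, adjusted p = 0.537 with an estimated correlation). Mki67 had a log2 fold change of 2.13 ± 0.26. Gonadal identity genes rose in FIP, 6 of 6 (camera adjusted p = 4.16e-05, adjusted p = 0.109 with an estimated correlation) in females. In males they rose too, 5 of 6 (camera adjusted p = 0.00511, adjusted p = 0.185 with an estimated correlation). Inguinal identity genes fell in males, 7 of 8 with 1 higher (camera adjusted p = 0.00583, adjusted p = 0.253 with an estimated correlation). Ribosomal protein genes fell in males, 27 of 27 (camera adjusted p = 6.31e-08, adjusted p = 0.594 with an estimated correlation). In females they fell too, 19 of 27 (22 lower adjusted over the list alone, camera adjusted p = 0.000878, adjusted p = 0.761 with an estimated correlation). The ribosomal call ended under quantile normalization (adjusted p = 0.323). Complement genes fell in males, 9 of 11 with 1 higher (camera adjusted p = 0.00138, adjusted p = 0.383 with an estimated correlation). In females they fell as well, 8 of 11 with 2 higher (camera adjusted p = 0.0114, adjusted p = 0.474 with an estimated correlation). The complement call ended under quantile normalization (adjusted p = 0.0965). Chemokine and cytokine genes fell in males, 14 of 21 with 4 higher (camera adjusted p = 0.000101, adjusted p = 0.329 with an estimated correlation). Cholesterol synthesis genes rose, 12 of 18 (camera adjusted p = 0.00119, adjusted p = 0.556 with an estimated correlation). In females collagen genes fell, 9 of 12 with 3 higher (camera adjusted p = 0.0219, adjusted p = 0.683 with an estimated correlation). The collagen call ended under quantile normalization (adjusted p = 0.169) and without replicate 3 of F_FIP (adjusted p = 0.0515). Matrix remodelling genes fell in female FIP, 13 of 24 with 2 higher (2 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.00180, adjusted p = 0.397 with an estimated correlation). The matrix remodelling call ended under quantile normalization (adjusted p = 0.0722). Of the HOX genes in females higher were 15 of 31 with 4 lower (camera adjusted p = 0.00861, adjusted p = 0.398 with an estimated correlation). The HOX gene call ended under quantile normalization (adjusted p = 0.0517).

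Immediate early genes were higher in FIP than in DPP4_pos, 11 of 18 with 4 lower in females (camera adjusted p = 0.00125, adjusted p = 0.545 with an estimated correlation). In males 15 rose and 3 fell (camera adjusted p = 1.82e-05, adjusted p = 0.398 with an estimated correlation). In male FIP 10 of 10 mesothelial markers were higher (camera adjusted p = 0.000515, adjusted p = 0.219 with an estimated correlation). Msln had a log2 fold change of 4.64 ± 0.39. So were 10 of 10 endothelial markers (camera adjusted p = 3.17e-05, adjusted p = 0.397 with an estimated correlation). Emcn had a log2 fold change of 2.82 ± 0.29. Mural markers were higher in male FIP, 7 of 9 with 2 lower (camera adjusted p = 0.0384, adjusted p = 0.397 with an estimated correlation). The mural call ended under TMM scaling (adjusted p = 0.0506), under quantile normalization (adjusted p = 0.0796) and without replicate 2 of M_FIP (adjusted p = 0.0506). In female FIP 8 of 10 endothelial markers were higher and 1 lower (camera adjusted p = 0.0261, adjusted p = 0.674 with an estimated correlation). The female endothelial call ended under quantile normalization (adjusted p = 0.0749) and without replicate 3 of F_DPP4_pos (adjusted p = 0.074). Adipocyte markers were higher there, 5 of 7 (6 higher adjusted over the list alone, camera adjusted p = 0.0317, adjusted p = 0.511 with an estimated correlation). The female adipocyte call ended under quantile normalization (adjusted p = 0.0718) and without replicate 3 of F_DPP4_pos (adjusted p = 0.0905). Epithelial markers were lower in female FIP than in F_DPP4_pos, 7 of 9 (camera adjusted p = 0.0141, adjusted p = 0.397 with an estimated correlation). The test called 6486 genes in females, 3211 higher and 3275 lower, and 9439 in males, 4736 higher and 4703 lower. Past 2-fold 1019 were higher and 984 lower in females, and 2030 and 1638 in males.

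**Figure D3:**
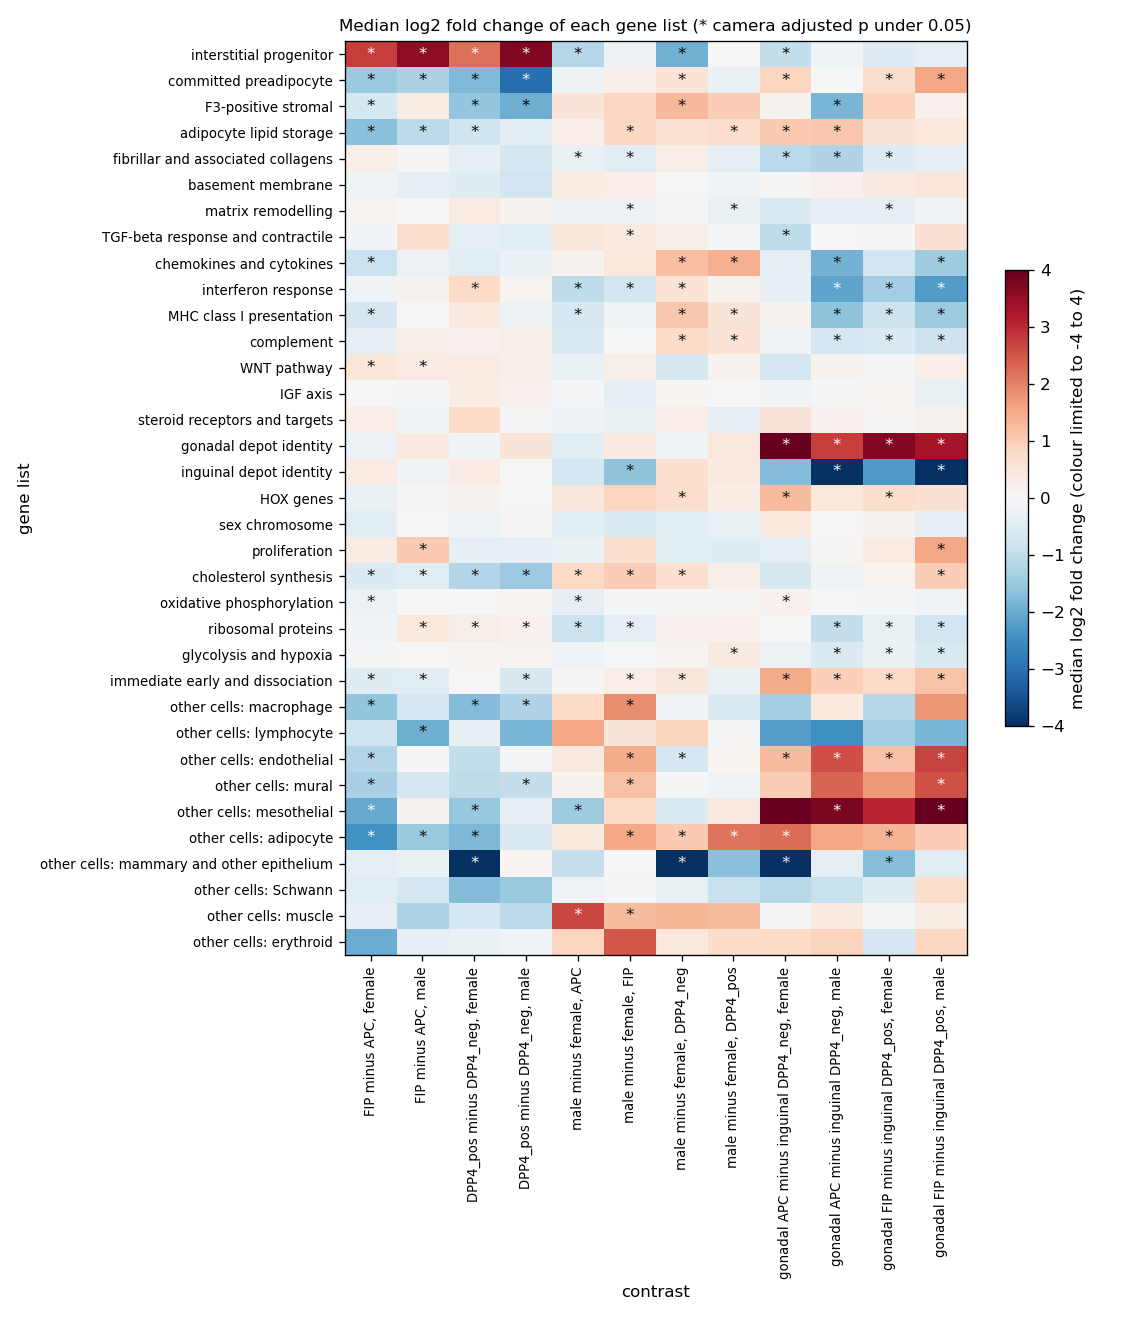
Median log2 fold change of each of the 35 gene lists in each of the 12 comparisons, from blue (lower) to red (higher), with an asterisk where camera at the preset correlation of 0.01 gave an adjusted p under 0.05. The test marked 142 of the 420 squares, and the 1 marked square whose median turned sign under quantile normalization was ribosomal proteins for DPP4_pos against DPP4_neg in females (0.23 to -0.02).

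Of the 35 lists, 29 were called in at least 1 comparison. The lists for basement membrane, the IGF axis, steroid receptors and their targets, sex chromosome genes, Schwann cells and erythroid cells were called in none by camera at the preset correlation. Camera asks for a shift in 1 direction, so members that go opposite ways, as Xist and Ddx3y do between the sexes, can cancel. A list without a call can therefore hold genes that differ strongly.

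The differences between the sexes in each comparison were tested directly. Csf2, a colony stimulating factor gene, had a male difference between FIP and APC that exceeded the female one by 5.46 ± 0.41 SE on the log2 scale (limma, Benjamini-Hochberg adjusted p = 1.63e-09), and Cxcl13, a B cell chemokine gene, differed by -5.85 ± 0.29 for APC against DPP4_neg. The effect of FIP against APC differed between the sexes in 1566 genes, 792 with a higher and 774 with a lower value in males. For DPP4_pos against DPP4_neg 4205 genes differed (2380 and 1825), for APC against DPP4_neg 6223 (3274 and 2949) and for FIP against DPP4_pos 5066 (2280 and 2786). With library weights 2946 genes differed for FIP against APC.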

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

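The counts of other splits and the tests of explanations in this part were chosen only after the results were seen. The effects of 4 comparisons differed between males and females by limma's test of the difference itself, with Benjamini-Hochberg adjustment. Each gene value below is the male minus the female log2 fold change, over 3 libraries in each group. Fitted values of genes near 0 in a group depend on the pseudocount and are no bounds.

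For FIP against APC 1566 genes differed. The highest values were 5.46 for Csf2, 4.15 for Prrt4, 3.56 for Ankrd1, 3.53 for Papln and 3.30 for Cilp. The lowest were -4.42 for Clic6, -4.37 for Tmem132b, -3.06 for Necab1, -2.56 for Pla2g7 and -2.47 for Alcam. The SE of these 10 values lay between 0.21 and 0.72. The call for Necab1 ended with a pseudocount of 0.25 (limma adjusted p = 0.108) and with edgeR (adjusted p = 0.0515), in a range over all alternatives from 2e-06 to 0.108.

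For DPP4_pos against DPP4_neg 4205 genes differed. The highest values were 7.21 for Cldn3, 6.51 for Gipc2, 6.28 for Krt7, 6.06 for Ido1 and 5.86 for Nxph3. The lowest were -3.86 for Npy1r, -3.74 for Spon1, -3.68 for S100a9, -3.68 for Ltf and -3.61 for Ubd. The SE lay between 0.29 and 1.14. Cldn3 and Krt7 are in the list of epithelial markers. Krt7 lay at 450, 1131 and 689 in F_DPP4_neg and at most at 3.06 in a M_DPP4_neg library. Their values may therefore follow the epithelial transcripts in F_DPP4_neg described below. Cldn3 was also higher in M_DPP4_pos (83.1 to 113) than in M_DPP4_neg (3.70 to 4.08). The call for S100a9 ended with a pseudocount of 0.25 (limma adjusted p = 0.11), edgeR (adjusted p = 0.426) and DESeq2 (adjusted p = 0.112). It also ended without replicate 2 of F_DPP4_neg (limma adjusted p = 0.0695) and without replicate 1 of F_DPP4_pos (adjusted p = 0.0603), in a range over all alternatives from 0.000844 to 0.426.

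For APC against DPP4_neg 6223 genes differed. The highest values were 10.99 for Krt8, 10.95 for Dmbt1, 10.28 for Gria1, 8.97 for Enpp6 and 8.94 for Nxph3. The lowest were -6.90 for Hoxa11, -6.62 for Hoxa11os, -6.36 for Hoxc10, -6.17 for Nrn1 and -5.85 for Cxcl13. The SE lay between 0.29 and 0.80. Krt8 and Dmbt1 averaged 4567 and 2740 in F_DPP4_neg against 0.681 and 1.02 in M_DPP4_neg. Their values may follow the epithelial transcripts in F_DPP4_neg as well. With edgeR the calls for Dmbt1 (adjusted p = 0.222, range over all alternatives 2.65e-15 to 0.222) and Hoxa11os (adjusted p = 1, range 1.79e-12 to 1) ended.

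For FIP against DPP4_pos 5066 genes differed. Among the highest values were 7.45 for Krt8, 6.5 for Cadps, 6.24 for Cldn4 and 5.38 for Enpp6. The lowest were -7.09 for Hoxa11os, -6.83 for Cntn1, -6.02 for Cxcl5, -5.40 for Hoxc10 and -5.27 for Il18r1. The SE lay between 0.34 and 1.11. Krt8 and Cldn4 averaged 141 and 127 in F_DPP4_pos against 1.14 and 0.752 in M_DPP4_pos, so epithelial transcripts may enter these values too. With edgeR the call for Cldn4 ended (adjusted p = 0.0612, range over all alternatives 5.88e-06 to 0.0612).

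For each of these 4 counts, 100 splits of the libraries within each sex were taken from 200 distinct ones, the real split included. For FIP against APC 10 splits called as many genes as the real 1566, with 7159 as the highest other count. For DPP4_pos against DPP4_neg 8 did (real 4205, highest other 5470), for APC against DPP4_neg 8 (real 6223, highest other 10473) and for FIP against DPP4_pos 8 (real 5066, highest other 7558). The other splits that called as many, 9, 7, 7 and 7, all kept the groups of 1 sex intact, which brings that sex's own difference into the difference between the sexes. These counts therefore do not decide whether chance can be excluded. The counts of 7159, several times the real one, and of 10473 came from splits that exchanged the groups in 1 sex. Such an exchange turns the effect that both sexes share into a difference between them, so these counts reflect the structure of the groups themselves.

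Each comparison of 2 groups had 10 splits, 1 of which, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The real split called 5719 genes for FIP against APC in females (highest other 0) and 5355 in males (highest other 1). For DPP4_pos against DPP4_neg it called 7216 in females (highest other 1, splits that part as many same-numbered pairs included) and 7334 in males (highest other 6). Male against female gave 6452 in APC, 5404 in FIP, 8332 in DPP4_neg and 7638 in DPP4_pos, with highest others of 0, 0, 3 and 4. APC against DPP4_neg gave 8569 in females and 9599 in males, with highest others of 1 and 0. FIP against DPP4_pos gave 6486 and 9439, with highest others of 1 and 1.

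Female DPP4_neg libraries held epithelial transcripts, with Epcam at 803, 1913 and 1149 in replicates 1, 2 and 3, and 7 of the 9 tested epithelial markers averaged at least 100. Reads carried over from another group's library were argued against, since the highest group outside the female inguinal depot reached at most 34.5% of the F_DPP4_neg mean for any of the 9 markers. Of 56 other genes at least 16-fold above every group outside that depot, 37 (66.1%) had replicate ratios within 0.5 (log2) of those of the markers, against 1.5% of 9091 genes with a mean of at least 100. Epithelial cells among the sorted cells are a candidate explanation, although a PDGFRb gate should remove them. A difference in sex or depot stays open and was not tested.

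Dpp4 in F_DPP4_neg replicates 1, 2 and 3 lay at 22.3%, 11.3% and 6.09% of its F_DPP4_pos mean, against 1.59% for the male groups. All 42 other genes at least 16-fold higher in male DPP4_pos had a smaller log2 fold change in females, which their choice on male values favours, and 39 (92.9%) were highest in replicate 1, the F_DPP4_neg library with the highest Dpp4. Of 14 other interstitial progenitor genes lower in male than female DPP4_neg, 6 of them among the 42, 13 (92.9%) were highest in that library too, Dact2 being highest in replicate 2, so DPP4_pos cells left among the F_DPP4_neg cells may account for part of both sets. Members did not all follow the Dpp4 shares, since Fn1, Dact2 and Wnt2 lay at 76.1%, 51.2% and 34.9% of their F_DPP4_pos means in replicate 3 (male groups 12.3%, 15.3% and 10.9%). Mixing DPP4_pos cells into DPP4_neg cells shrinks a difference and does not turn it. The 488 of 4653 genes called in both sexes (10.5%) that went in opposite directions argue against this mixing as their only cause. Cells of another type, such as the epithelial candidates above, could turn a difference. Both that and a difference between the sexes stay open, untested.

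Female libraries held Y-linked reads, most in F_APC, where Ddx3y, Eif2s3y, Kdm5d and Uty lay at 3.58% to 4.50% of their M_APC means. For reads shared with the X-linked copies, the difference of each Y-linked gene between F_APC and F_DPP4_pos was set against that of its copy. The ratio was 2.04 for Ddx3y, 2.52 for Eif2s3y, 6.42 for Kdm5d and 1.75 for Uty, against a limit of 1.5. No error was computed for these ratios. Uty averaged only 9.77 ± 2.99 in F_APC and 3.99 ± 1.93 in F_DPP4_pos (SD, n = 3). The test therefore does not exclude shared reads, at least for Uty. Exchange of reads in both directions was argued against by Xist, which reached at most 0.0390% of the female mean in a male library. Male RNA or reads in the female libraries would give the 4 genes about the same share of the male level, and the largest share was 1.26, 1.2 and 1.35 times the smallest in F_APC, F_DPP4_neg and F_DPP4_pos. In F_FIP it was 1.57 ± 0.46 (SE), past the limit of 1.5 by less than its error, so this stays open, and no biological explanation was tested.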

How the results depend on the processing

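The fits without genes 16-fold above the other groups and the list tests without each library were chosen after seeing the data. No named gene or list that was still called under an alternative had turned its direction, and the other genes were not checked for this. Quantile normalization ended the female ribosomal protein call for DPP4_pos against DPP4_neg and turned its median from 0.23 to -0.02. Counted once per named gene, contrast and alternative, 31903 results stayed on their side of the threshold, 726 lost a call and 169 gained a call, and leaving out a library accounted for 410 of the lost calls.

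Requiring an absolute log2 fold change of at least 1 left 1692 and 1572 genes for FIP against APC in females and males, 2589 and 2579 for DPP4_pos against DPP4_neg, 3021 and 3600 for APC against DPP4_neg, and 2003 and 3668 for FIP against DPP4_pos. For male against female it left 1771 in APC, 1559 in FIP, 2608 in DPP4_neg and 2083 in DPP4_pos. For the differences between sexes it left 525 for FIP against APC, 1649 for DPP4_pos against DPP4_neg, 2557 for APC against DPP4_neg and 1722 for FIP against DPP4_pos. The stricter criterion itself lowered these counts. Library weights raised the count for the sex difference in FIP against APC from 1566 to 2946, and the cause was not tested.

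Of the 142 list calls, 2 held with an estimated correlation, fry made 286, TMM scaling made 144 and quantile normalization 137. TMM scaling ended 1 of the 142 and quantile normalization 22. Quantile normalization moved the median of all genes from -0.02 to 0.11 (log2) for female APC against DPP4_neg, the 1 contrast with a shift over 0.1. Leaving out a library gave 142 to 149 list calls and ended 17 of the 142 in at least 1 case.

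Over genes with a mean of at least 100, the correlation of fold changes across genes was higher, and the cause was not tested. Between FIP against APC and DPP4_pos against DPP4_neg it was 0.542 in females and 0.658 in males. Between the sexes it was 0.791 for FIP against APC, 0.714 for DPP4_pos against DPP4_neg, 0.618 for APC against DPP4_neg and 0.763 for FIP against DPP4_pos. For male against female it was 0.800 between APC and FIP, 0.40 between APC and DPP4_neg, 0.405 between APC and DPP4_pos, 0.404 between FIP and DPP4_neg, 0.506 between FIP and DPP4_pos and 0.684 between DPP4_neg and DPP4_pos.

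With the replicate number as a block, counts stayed within 1.5 times, for example 5585 for female FIP against APC, 7101 for female DPP4_pos against DPP4_neg and 1496 for the sex difference in FIP against APC. It ended 7 calls of named genes and started 6. Outside female DPP4_neg and DPP4_pos the libraries share only a number, and same-numbered libraries correlated between -0.173 and 0.201 over all pairs of groups. Leaving out each library in turn kept every count within 1.5 times of the full count. As a ratio of highest to lowest, the widest range was 1185 to 1557 for the sex difference in FIP against APC. Without 61 genes high in the female inguinal libraries, 7151 genes were called for female DPP4_pos against DPP4_neg and 8268 for male against female DPP4_neg. Removing called genes itself lowers such counts, so they do not show how other cells in these libraries affect the remaining genes. DESeq2 gave no adjusted p for 845 genes in the sex difference in FIP against APC. Depth limits the low genes most, and the female APC libraries, at 9152470 to 13394000 reads, were among the shallowest.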

Other observations

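The genes in this part were chosen after their values were seen, and none of its counts was planned. In both depots and both sexes 1004 genes were higher in FIP or DPP4_pos than in APC or DPP4_neg, where the genes higher in both sexes in each depot, 1861 and 2068, would share 265 if the depots were independent. Another 672 were lower, against 211 for the 1464 and 2097 genes lower in both sexes. Sema3c, a secreted semaphorin gene, had log2 fold changes of 3.0 and 3.49 for FIP against APC in females and males, and of 2.80 and 3.47 for DPP4_pos against DPP4_neg (SE 0.21, n = 3 and 3). The annexin gene Anxa3 had 2.79, 2.86, 2.56 and 4.23 in the same order (SE 0.22). Cxcl14, a chemokine gene, had -2.96, -2.48, -3.25 and -4.78 (SE 0.14).

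Fewer genes went opposite ways in the depots. Higher in FIP and lower in DPP4_pos in both sexes were 52 genes, against 269 for independent depots by the same count, and 31 were lower in FIP and higher in DPP4_pos, against 209. The tetraspanin gene Cd9 had log2 fold changes of 1.76 and 3.94 for FIP against APC in females and males, and of -1.14 and -1.07 for DPP4_pos against DPP4_neg (SE 0.12, n = 3 and 3). Gfra2 had 3.90 and 4.90, and -2.42 and -1.01 (SE 0.31). In the other direction Prelp, a proteoglycan gene, had -0.74 and -0.71, and 1.70 and 0.80 (SE 0.14). The gates that separated FIP from APC were not given. Whether the sort itself set a difference of any gene here, such as Cd9, is therefore not known.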
